A study of Mus musculus with 74 samples.

How the data were processed

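RNA of the whole main olfactory epithelium (MOE, the nasal tissue that holds the olfactory sensory neurons) was measured in mice of 3 Trim66 models, in 28 bulk libraries and in 2 single-cell libraries. Per the labels, the models were a Trim66 knockout line without a Cre driver, called the germline knockout here, a floxed Trim66 allele with Foxg1-Cre, and a floxed allele with Goofy-Cre. As background, Foxg1 is a transcription factor active from the olfactory placode onwards, and Goofy (Gfy) encodes a Golgi protein of olfactory sensory neurons, so that the Foxg1 driver is expected to act earlier than the Goofy driver. Each model had heterozygous and homozygous libraries, and the heterozygous libraries served as the control because no wild-type RNA library is among the samples. The labels do not say whether replicates were separate animals, so that the p-values measure the spread between samples, which may be technical. Sex, age and litter were not given in the sources used here.

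Per the labels, bulk libraries were made from mRNA with commercial kits. Per the submitters' processing notes, the tools were Trimmomatic 0.39, HISAT2 2.1.0, featureCounts of Subread 2.0.1 and DESeq2 1.40.1 with the mm10 mouse genome; the order of the steps, the counting strand and the handling of reads with several matches were not given in the sources used here. The deposited bulk tables of normalized counts hold a signal: gene counts that the authors divided by a size factor per library. This was tested on the values, and every column turned out to be a whole multiple of a single step, so that the whole reads could be recovered for 100% of values within a tolerance of 0.1 reads. The plan, written before the data were examined, allowed for either raw counts or counts scaled by size factors, and the second form applied. The deposited TPM tables, also made by the authors, hold TPM (transcript abundance corrected for gene length, with the same total in each library), and their values equal the normalized counts divided by the gene length of the table and rescaled to the same total. The genes tested were annotated as protein-coding genes, polymorphic pseudogenes or unprocessed pseudogenes. Each model had its own table with its own controls, and the tables were never merged. Columns were matched to libraries through the samples' descriptions, and 0 columns were left without a library.

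Per the labels, single cells were dissociated with trypsin and DNase I, with transcription inhibitors in the solutions, and sequenced as droplet libraries of transcript 3′ ends. The deposited single-cell matrices hold raw UMI counts per gene and barcode (UMI, unique molecular identifier, a count of molecules); their header names Cell Ranger 6.1.2, and the submitters' processing notes also name STAR and Seurat 4.3.0. Which barcodes the authors kept was not given in the sources used here. Both single-cell libraries come from the germline knockout line, 1 heterozygous and 1 homozygous.

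In the bulk data, genes with a mean normalized count of at least 10 over the libraries of a table were tested, homozygous against heterozygous, with limma 3.58.1 in R 4.3.3 (eBayes with trend and robust variance) on log2(normalized count + 1). Tests were two-sided, with Benjamini-Hochberg adjustment over the genes of a table and a threshold of 0.05. Fold changes are on this log2 scale, which understates the change of genes with low counts, and a positive value means higher in homozygous libraries. Olfactory receptor (OR) genes were taken by symbol, pseudogenes included. The share of normalized counts on OR genes and the effective number of ORs, which is the exponential of the Shannon entropy of a library's OR counts, were compared by an exact two-sided permutation test over libraries. Gene lists fixed before the data were examined were tested against all other genes with camera (limma, preset inter-gene correlation 0.01) and again with the correlation estimated for each list. Of 33 lists, 31 were tested in each model: markers of mature olfactory sensory neurons (OSNs), immature OSNs, neuronal progenitors, horizontal basal cells, sustentacular cells, Bowman glands, microvillous cells, ensheathing glia, macrophages, neutrophils, lymphocytes, erythroid cells, endothelium, fibroblasts and osteogenic cells, and respiratory epithelium; cell cycle, OR choice regulators, Polycomb with YY1, TIF1 with HP1 proteins, unfolded protein response, neuronal activity, axon guidance, dorsal zone, ventral zone, clustered protocadherins, trace amine-associated receptors (TAARs), vomeronasal receptors, MS4A receptors, germline genes, and class I and class II ORs. The other two, reference ORs and sex-linked genes, were only described. Class I ORs were those of the class I region of chromosome 7. ORs changed in all 3 models were counted beside the number that independent lists would share, with no test across tables.

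The named genes follow a rule fixed before the data were examined. Trim66 comes first; then, among genes past the threshold with a mean normalized count of at least 50, the 6 ORs and the 6 other genes of each sign with the largest log2 fold change (predicted genes, clones and pseudogenes other than ORs left out); then, for each list, the 2 members past the threshold with the smallest adjusted p; then the reference ORs, the sex-linked genes and, as a group, the genes other than ORs within 5 Mb of Trim66. In single cells the rule takes 8 other genes and 5 ORs of each sign with the largest ratio of CPM (UMI counts scaled to the same total for each class and library) in mature OSN-like cells, among genes at 50 CPM or more in at least 1 library. Symbols and Ensembl identifiers are those of the tables, and positions are those of the mm10 annotation.

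Single cells with at least 500 genes and under 20% mitochondrial counts were kept, in scanpy 1.11.5 with anndata 0.12.19 and Python 3.11.15. Doublets were scored with Scrublet, and the highest scores of each library were removed at a nominal rate proportional to its number of cells, which came to 11.9% of heterozygous and 19.5% of homozygous cells. The 2 libraries were clustered together on 2000 highly variable genes, 30 principal components and 15 neighbours with leidenalg 0.10.2 at resolution 1; ORs, TAARs, vomeronasal receptors, H2-M genes, mitochondrial genes, Trim66, GFP and sex-linked genes were excluded from the clustering. A cluster was named X-like when at least 3 markers of a class, and more than of any other class, were among its 50 leading genes and its own markers led its top 10 genes. Leading genes were ranked by the fold of CPM plus 100 against the median over clusters. A cluster whose top genes held 3 or more secretory gland genes stayed unnamed. An OR was counted as held by a cell at 3 or more UMIs. Cells were also thinned to 3000 UMIs each, and cells with fewer UMIs were left out of all thinned results. Different top ORs were counted over equal numbers of cells in 20 draws. Intervals for shares are exact Clopper-Pearson 95% intervals, and intervals for counts are exact Poisson intervals; they and the floor of 3 counts cover counting error only. With 1 library per genotype, single cells were described without a test.

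The fit was tested on simulated counts with known changes in 200 genes, made from means and dispersions of the heterozygous libraries. The changed genes had a mean of at least 50 and rose or fell at random. Genes with fewer counts and changes as many and as one-sided as the real ones were therefore not covered. In the germline, Foxg1-Cre and Goofy-Cre tables, limma recovered 92.5%, 82.1% and 85.1% of 2-fold changes, and 11, 7 and 9 unchanged genes were called. At 1.5-fold, recovery was 59.7%, 50.8% and 64.2%.

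Alternatives fixed before the data were examined were a pseudocount of 5, no filter, rescaling to the same total, the TPM table (log2(TPM + 0.1), mean TPM of at least 0.5), replicate number as a block, the mature OSN level as a covariate, an adjusted p under 0.01, edgeR 4.0.16 and DESeq2 1.42.0 on the recovered reads, each library left out in turn, other OR calls, cell filters, resolutions (0.5 and 2), doublets kept and thinning. Several choices were made after the data were seen: a sex term read from Ddx3y, heterozygous replicates 3 and 4 of the Foxg1-Cre model averaged, edgeR and DESeq2 counts for ORs, the fold against the median used to name clusters, the gland rule, the nominal doublet rate (taken because the automatic threshold of Scrublet marked only 65 of 14917 heterozygous cells), the count of ORs without the shallow mature OSN-like cluster, and the margin of 2 standard errors in the weighing of the OR share. Other tools were numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, igraph 0.11.9, scikit-learn 1.9.0, matplotlib 3.10.9 and statmod 1.5.0. The ChIP-seq, ATAC-seq, CUT&Tag and Hi-C samples of the series were not analysed here.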

Results

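RNA of the main olfactory epithelium (MOE) was compared between mice heterozygous and homozygous for a Trim66 mutation. TRIM66 is a chromatin-associated protein of the TIF1 family, and the study asked how its loss changes the expression of olfactory receptors (ORs), of which a mature olfactory sensory neuron (OSN) normally transcribes a single gene. Bulk RNA sequencing covered the germline knockout with 5 heterozygous and 5 homozygous libraries, the Foxg1-Cre model with 4 and 4, and the Goofy-Cre model with 5 and 5. Recovered reads per library ran from 25.5 M to 37.2 M in the germline knockout, from 36.3 M to 52.1 M in the Foxg1-Cre model and from 57.8 M to 77.3 M in the Goofy-Cre model. The 10 most abundant genes of a library held between 4.44% and 12.1% of its reads. The Y-linked gene Ddx3y exceeded 100 normalized counts in 2 of 5 heterozygous and 2 of 5 homozygous germline libraries. In the Foxg1-Cre model it did so in 3 of 4 and 2 of 4 libraries, and in the Goofy-Cre model in 4 of 5 and 4 of 5. Ddx3y, Eif2s3y, Kdm5d and Uty did not pass the test in any model (Ddx3y limma adjusted p = 0.903, 0.657 and 0.916). Droplet-based single-cell RNA sequencing covered 1 heterozygous and 1 homozygous library of the germline knockout.

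The germline comparison asks what changes in the MOE when every cell lacks functional Trim66. Trim66 itself (ENSMUSG00000031026.15, mm10 chromosome 7, 109449006 to 109508134) had a normalized count of 12687 ± 2335 (SD, n = 5) in heterozygous and 12991 ± 1664 (SD, n = 5) in homozygous libraries, a difference that did not pass the test (log2 fold change 0.04, SE 0.12, limma adjusted p = 0.859). The deleted exons are not given in the sources used here, so that counts over the whole gene could check neither the deletion nor the labels. Of 1070 tested OR genes, 944 fell and 67 rose, with a median log2 fold change of -3.45. Among all 16610 tested genes, 2408 passed the threshold in limma, 701 higher and 1707 lower. With edgeR on the recovered reads 2441 genes passed, and with DESeq2 3003. With the mature OSN level of each library as a covariate 988 passed, 133 higher and 855 lower. From TPM values the count was 1396, of which 273 were higher (19.6% of calls, against 29.1% from normalized counts). The number of higher genes was 447 without heterozygous replicate 3, 459 without homozygous replicate 4 and 1054 without homozygous replicate 5. Within 5 Mb of Trim66, with ORs left out, 4 of 67 tested genes rose and 4 fell, which is 11.9% against 8.98% of the genes elsewhere that are not ORs. For every germline gene named below as risen or fallen, all 5 homozygous libraries lay on that side of the heterozygous mean.

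The largest rise among germline ORs was that of Olfr427 (ENSMUSG00000059371.4, chromosome 1, 174096891 to 174103224), a class II receptor gene. Its normalized count rose from 26.9 ± 7.64 to 4856 ± 1159 (SD, n = 5 each), a log2 fold change of 7.45 (SE 0.21, adjusted p = 7.7e-12). Its neighbour Olfr258-ps1, an annotated pseudogene, rose by 6.55 on the log2 scale, although reads shared with related receptors make its own level uncertain. Olfr51 (ENSMUSG00000060918.2, chromosome 11, 51003596 to 51009676) rose by 5.43 and Olfr464 (ENSMUSG00000060787.9, chromosome 11, 87913268 to 87920967) by 4.95. Olfr1329 (ENSMUSG00000096705.1, chromosome 4, 118916524 to 118917465) rose by 5.24 and Olfr525 (ENSMUSG00000061489.3, chromosome 7, 140320858 to 140327625) by 4.75. The largest fall was that of Olfr250 (ENSMUSG00000049864.2, chromosome 9, 38366896 to 38371355), from 298.5 ± 57.3 to 1.38 ± 2.07 (SD, n = 5 each; log2 fold change -7.30, SE 0.41, adjusted p = 1.1e-09). Only 6 reads were left over the 5 homozygous libraries, and homozygous replicate 1 stood at 4.98 normalized counts. Olfr1463, Olfr1443, Olfr810, Olfr329 and Olfr1321 also fell, with log2 fold changes from -6.97 for Olfr1463 to -6.66 for Olfr1321. Among the reference ORs, chosen because they are widely used in the field, Olfr1507 (MOR28; chromosome 14, 52488791 to 52495749) rose from 4591 ± 1187 to 12544 ± 1729 (SD, n = 5 each; log2 fold change 1.47, adjusted p = 3.6e-06). Olfr73, Olfr16, Olfr17, Olfr1509, Olfr2, Olfr15, Olfr160 and Olfr545 fell, Olfr73 the most at -5.78 and Olfr545 the least at -1.02. Neither Olfr1508 (adjusted p = 0.0842) nor Olfr78 (adjusted p = 0.302) passed, although Olfr1508 did so without heterozygous replicate 2 or 4.

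The strongest rise outside the ORs in the germline knockout was that of H2-M1. H2-M1 (ENSMUSG00000037334.2, chromosome 17, 36670008 to 36672219) encodes a non-classical major histocompatibility protein known from vomeronasal neurons. It rose from 48.4 ± 37.6 to 12033 ± 3469 (SD, n = 5 each; log2 fold change 8.28, SE 0.57, adjusted p = 6.9e-06). Its relative H2-M10.4 (ENSMUSG00000048231.14, chromosome 17, 36458917 to 36462334) had 0 reads in heterozygous libraries and was at least 264-fold higher in homozygous ones, against a floor of 3 counts over the group. H2-M9 rose by 6.08 on the log2 scale; reads shared between these paralogs make the separate levels uncertain. Vmn2r27 (ENSMUSG00000072778.3, chromosome 6, 124189756 to 124231856), a vomeronasal pheromone receptor gene, rose from 102 ± 83.2 to 3520 ± 1881 (SD, n = 5 each; log2 fold change 5.22, adjusted p = 1.2e-04), although heterozygous replicate 3 stood at 248.0. AW551984 (ENSMUSG00000038112.15, chromosome 9, 39587396 to 39604403) rose by 4.12 and the trace amine receptor gene Taar2 (ENSMUSG00000059763.4, chromosome 10, 23938572 to 23941583) by 3.25. The largest falls outside the ORs by symbol were those of the receptor-like gene OR5BS1P (-5.69), of Taar7e (-3.70), Taar7f (-3.39), Taar7b (-2.28) and Taar7d (-2.06), which share much of their sequence, and of the neuropeptide gene Avp (-2.36).

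In the germline knockout 13 of 31 lists passed camera with the preset correlation. Only class I ORs (adjusted p = 0.0243 with an estimated correlation) and class II ORs (2.6e-04) held with an estimated one. With each library left out in turn 8 to 12 lists passed, and 13 of 100 splits, the real one included, gave at least 13. In each model the genes that a list is compared with include the fallen ORs. Lists with small rises may pass as higher for that reason, and camera was not rerun without ORs. Class I ORs had 4 of 118 members higher and 105 lower (5 and 106 adjusted over the list alone; median -2.84), and class II ORs had 63 of 952 higher and 839 lower (74 and 848 adjusted over the list alone; median -3.52). Mature OSN markers, such as the channel subunit gene Cngb1 and the stomatin relative Stoml3, fell in 11 of 14 members (12 adjusted over the list alone; median -0.39; adjusted p = 0.410 with an estimated correlation). Cngb1 (ENSMUSG00000031789.17, chromosome 8, 95239045 to 95306585) fell from 9833 ± 1534 to 5946 ± 577 (SD, n = 5 each; log2 fold change -0.72, SE 0.10, adjusted p = 6.1e-05). Immature OSN markers were higher in 4 of 12 (5 adjusted over the list alone; median 0.21), with Stmn4 at 0.53 and Cxcr4, which did not pass from TPM values, at 0.41; the list had an adjusted p = 0.410 with an estimated correlation. Progenitor markers were higher in 6 of 9 (7 adjusted over the list alone; median 0.41), including the transcription factor genes Hes6 (0.51) and Mxd3 (0.70), with an adjusted p = 0.410 with an estimated correlation. Cell cycle genes were higher in 9 of 14 (13 adjusted over the list alone; median 0.42), among them Ube2c (0.44) and Aurkb (0.53), again with an adjusted p = 0.410 with an estimated correlation. Horizontal basal markers were higher in 2 of 7 (3 adjusted over the list alone), microvillous markers in 2 of 8 (2 adjusted over the list alone) and vomeronasal receptors in 1 of 4, each at an adjusted p = 0.410 with an estimated correlation. Ensheathing glia markers were higher in 3 of 10 (7 adjusted over the list alone), among them Frzb (0.59) and Npy (0.68), with an adjusted p = 0.373 with an estimated correlation. Fibroblast and osteogenic markers were higher in 2 of 10 (2 adjusted over the list alone), with the cartilage collagen gene Col2a1 at 0.92, and had an adjusted p = 0.745 with an estimated correlation. Axon guidance genes were lower in 9 of 20 and higher in 1 (13 and 1 adjusted over the list alone; median -0.33), with Pcdh10 at -1.21 and Plxna3 at -0.78. Ventral zone genes were lower in 1 of 4 (3 adjusted over the list alone), the scaffold gene Dlg2 at -0.66; both of these lists had an adjusted p = 0.410 with an estimated correlation.

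The other germline lists did not pass. Lists without a called gene were Bowman gland, macrophage, neutrophil, lymphocyte, erythroid, endothelial, dorsal zone, clustered protocadherin and MS4A receptor genes. Sustentacular markers had 1 of 12 higher and 1 lower, and respiratory markers had 2 of 7 lower, the ciliary genes Ccdc39 (-0.41) and Foxj1 (-0.33), neither of which passed from TPM values. OR choice regulators had 3 of 24 lower, with the adenylyl cyclase gene Adcy3 at -0.60 (adjusted p = 7.3e-04). Polycomb genes had 1 of 14 higher, TIF1 genes 1 of 7 higher, and unfolded protein response genes 1 of 16 higher, which was Trib3 (0.84). Activity genes had 3 of 13 lower, including Pcp4l1 (-0.49) and Lrrc3b (-0.98), the latter not past the threshold from TPM values. TAARs had 3 of 11 higher and 6 lower (camera adjusted p = 0.0608), and germline genes had 1 of 5 lower. Median and mean differed in sign for OR choice regulators (0.03 and -0.03, test direction up) and activity genes (0.03 and -0.10, direction down).

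The Foxg1-Cre comparison asks the same of a deletion by a driver active in the early olfactory lineage and forebrain. Trim66 had 24723 ± 4236 normalized counts in heterozygous and 22184 ± 4563 in homozygous libraries (SD, n = 4 each; log2 fold change -0.16, SE 0.16, limma adjusted p = 0.565). Of 1099 tested ORs, 943 fell and 42 rose, with a median log2 fold change of -3.39. With the mature OSN level of each library as a covariate, 353 ORs were called lower, at a median OR log2 fold change of -2.83 and a median SE of 0.73 against 0.31 without it. Among all 16972 tested genes, 1902 passed, 399 higher and 1503 lower. With edgeR 1860 passed and with DESeq2 2608, of which 748 were higher. With the mature OSN level as a covariate 475 passed, 61 higher and 414 lower. The number of higher genes was 230.0 from TPM values, 677 without heterozygous replicate 2, 212 without heterozygous replicate 3, 214 without heterozygous replicate 4 and 225 without homozygous replicate 3. Heterozygous replicates 3 and 4 differed far less than any other pair of replicates of the same genotype and model (chi-square per gene 2.72, against 23.7 to 181.9), so that they may be technical replicates of 1 sample. With these 2 averaged, 1424 genes passed, 216 higher and 1208 lower, with 40 ORs higher and 923 lower. Among genes within 5 Mb of Trim66 that are not ORs, 0 of 68 tested rose and 3 fell, which is 4.41% against 5.78% of such genes elsewhere. For every gene named below as risen or fallen in this model, all 4 homozygous libraries lay on that side of the heterozygous mean.

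Olfr427 again had the largest rise among Foxg1-Cre ORs, from 44.6 ± 61.9 to 9459 ± 632 (SD, n = 4 each; log2 fold change 8.53, SE 0.72, adjusted p = 6.0e-05). Heterozygous replicate 2 alone held 137.4 of these counts, against 11.2 to 15.4 in the others. Olfr258-ps1 rose by 7.07, Olfr464 by 5.29 (adjusted p = 8.0e-08), Olfr51 by 5.24, Olfr421-ps1 by 4.96 and Olfr1329 by 4.82 on the log2 scale, and heterozygous replicate 2 also stood apart for Olfr421-ps1, at 89.8. Olfr239 (ENSMUSG00000093884.2, chromosome 17, 33191302 to 33202506) fell the most, from 889 ± 173 to 2.78 ± 1.88 (SD, n = 4 each; log2 fold change -8.10, SE 0.48, adjusted p = 9.6e-07). Olfr788, Olfr250, Olfr1443, Olfr224 and Olfr329 also fell, with log2 fold changes from -7.65 for Olfr788 to -7.07 for Olfr329, and for Olfr224 only 1 read was left over the homozygous libraries. Olfr1507 rose from 2750 ± 529 to 11149 ± 2543 (SD, n = 4 each; log2 fold change 2.01, adjusted p = 1.1e-05). The reference ORs Olfr73 (-5.95), Olfr16, Olfr17, Olfr2, Olfr1509, Olfr160, Olfr15 and Olfr78 (-1.08) fell. Neither Olfr1508 (adjusted p = 0.518) nor Olfr545 (adjusted p = 0.0700) passed, although Olfr545 did so without heterozygous replicate 2.

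H2-M1 rose from 18.4 ± 5.32 to 20003 ± 3407 in the Foxg1-Cre model (SD, n = 4 each; log2 fold change 10.04, SE 0.21, adjusted p = 4.2e-09). H2-M10.4 was at least 301-fold higher, with 0 heterozygous reads, and H2-M9 rose by 6.30 on the log2 scale. Vmn2r27 rose from 72.6 ± 49.7 to 2894 ± 561 (SD, n = 4 each; log2 fold change 5.49, adjusted p = 2.1e-06). The signal recognition particle gene Srp54b rose by 3.72 with heterozygous replicate 4 at 73.3 against 4.33 to 13.3 in the others, and AW551984 rose by 3.56. The largest falls outside the ORs by symbol were those of OR5BS1P (-5.89), Taar7f (-3.499), Taar7e (-3.46), Xlr3a (-3.30), Xlr3b (-2.28) and Taar7b (-2.10); Xlr3a and Xlr3b are X-linked paralogs whose shared reads leave their separate levels uncertain.

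In the Foxg1-Cre model 9 of 31 lists passed, and only class II ORs held with an estimated correlation (adjusted p = 0.0223). With each library left out in turn 10 to 14 lists passed, and 18 of 35 splits, the real one included, gave at least 9. Class II ORs had 39 of 978 members higher and 840 lower (52 and 870 adjusted over the list alone; median -3.42). Class I ORs had 3 of 121 higher and 103 lower (6 and 107 adjusted over the list alone; median -2.98), with an adjusted p = 0.135 with an estimated correlation. Mature OSN markers were lower in 9 of 14 (13 adjusted over the list alone; median -0.52), the channel genes Cnga4 at -0.76 and Ano2 at -0.61, with an adjusted p = 0.363 with an estimated correlation. Progenitor markers were higher in 4 of 9 (8 adjusted over the list alone; median 0.37), with an adjusted p = 0.0795 with an estimated correlation. Cell cycle genes were higher in 10 of 14 (14 adjusted over the list alone; median 0.52), the cyclin gene Ccnb1 at 0.62, with an adjusted p = 0.324 with an estimated correlation. Neutrophil markers were higher in 7 of 9 (8 adjusted over the list alone; median 1.27), with an adjusted p = 0.324 with an estimated correlation. The neutrophil calprotectin gene S100a9 (ENSMUSG00000056071.12, chromosome 3, 90692632 to 90695721) rose from 1120 ± 318 to 2696 ± 747 (SD, n = 4 each; log2 fold change 1.27, SE 0.22, adjusted p = 0.00299). Erythroid markers were higher in 5 of 6 (6 adjusted over the list alone; median 1.39), with an adjusted p = 0.376 with an estimated correlation, and macrophage markers in 1 of 10 (4 adjusted over the list alone; median 0.34), with an adjusted p = 0.571 with an estimated correlation. Axon guidance genes were lower in 5 of 20 (11 adjusted over the list alone; median -0.42), Plxna3 at -0.82, with an adjusted p = 0.498 with an estimated correlation.

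The other Foxg1-Cre lists did not pass. Bowman gland, microvillous, ensheathing glia, lymphocyte, TIF1, unfolded protein response, dorsal zone, protocadherin and MS4A receptor genes held no called member. Immature OSN markers had 2 of 12 higher (camera adjusted p = 0.0610). Horizontal basal markers had 1 of 7 higher, endothelial markers 1 of 8, fibroblast markers 1 of 10, Polycomb genes 1 of 14 (Ezh2, 0.36, not past the threshold from TPM values), activity genes 1 of 13 and vomeronasal receptors 1 of 4. Sustentacular markers had 1 of 12 lower, respiratory markers 1 of 7 (Ccdc39, -0.50, not past the threshold from TPM values), OR choice regulators 2 of 24 (Adcy3 at -0.60), ventral zone genes 1 of 4 and germline genes 1 of 5. TAARs had 3 of 11 higher, including Taar2 (3.41) and Taar6 (1.50), and 6 lower. Median, mean and test differed in sign for sustentacular markers (0.04 and -0.05, direction down), respiratory markers (-0.07 and 0.01, direction down), OR choice regulators (0.01 and -0.06, direction down) and activity genes, whose median and mean both lay within 0.01 of 0 (direction up).

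The Goofy-Cre comparison asks whether deletion within the neuronal lineage is enough for these changes. Trim66 had 52194 ± 2837 normalized counts in heterozygous and 47957 ± 4899 in homozygous libraries (SD, n = 5 each; log2 fold change -0.13, SE 0.07, limma adjusted p = 0.243). Of 1125 tested ORs, 986 fell and 64 rose, with a median log2 fold change of -3.54. With the mature OSN level as a covariate, 375 ORs were called lower and 16 higher, at a median OR log2 fold change of -3.90 and a median SE of 1.18 against 0.29 without it. Among all 17491 tested genes, 3947 passed, 1462 higher and 2485 lower, so that 37.0% of the calls were rises. With edgeR 3922 passed and with DESeq2 4531. With the mature OSN level as a covariate 473 passed, 69 higher and 404 lower. From TPM values, 756 genes rose and 3331 fell, which is 18.5% rises. Of the 70 tested genes within 5 Mb of Trim66 that are not ORs, 13 rose and 6 fell, which is 27.1% against 17.7% of such genes elsewhere. All 5 homozygous libraries lay past the heterozygous mean, in the direction given, for every Goofy-Cre gene named as risen or fallen.

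Olfr427 rose from 30.6 ± 5.86 to 9699.5 ± 1658 in the Goofy-Cre model (SD, n = 5 each; log2 fold change 8.26, SE 0.15, adjusted p = 1.9e-13). Olfr258-ps1 rose by 7.43, Olfr464 by 5.25, Olfr447 (ENSMUSG00000045708.4, chromosome 6, 42908878 to 42914273) by 5.06, Olfr51 by 4.90 and Olfr1329 by 4.88 on the log2 scale; homozygous replicate 3 stood apart for Olfr51, at 8137. Olfr250 fell from 571 ± 205 to 0.678 ± 1.52 (SD, n = 5 each; log2 fold change -8.67, SE 0.44, adjusted p = 2.4e-09), with 4 reads left, all in homozygous replicate 3. Olfr224, Olfr55, Olfr239, Olfr1044 and Olfr639 also fell, with log2 fold changes from -7.85 for Olfr224 to -7.34 for Olfr639. Olfr1507 rose from 10438 ± 3910 to 31304 ± 3752 (SD, n = 5 each; log2 fold change 1.66, adjusted p = 9.4e-04). Of the 12 reference ORs, 2 rose and 10 fell: Olfr151 (M71), annotated as a polymorphic pseudogene, rose by 1.81 but did not pass without homozygous replicate 2, Olfr73 fell the most (-7.05), and Olfr1508 fell by 0.53 close to the threshold (adjusted p = 0.0478), a call lost when any of several libraries was left out.

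H2-M1 rose from 17.8 ± 8.58 to 15365 ± 1132 in the Goofy-Cre model (SD, n = 5 each; log2 fold change 9.79, SE 0.26, adjusted p = 9.3e-11). H2-M10.4 was at least 532-fold higher, with 0 heterozygous reads, and H2-M9 rose by 6.83 on the log2 scale. Vmn2r27 rose by 5.26, AW551984 by 3.82 and Taar2 by 3.503. Taar9 (ENSMUSG00000037424.6, chromosome 10, 24108488 to 24109534), a trace amine receptor gene, fell from 262 ± 49.5 to 4.65 ± 4.05 (SD, n = 5 each; log2 fold change -5.95, SE 0.54, adjusted p = 1.1e-06). OR5BS1P (-5.74), Taar7f (-3.97), Taar7e (-3.66) and Taar7b (-2.53) also fell, as did the hair keratin gene Krt25 (-2.55), for which heterozygous replicate 3 stood at 394.4 against 33.1 to 59.3 in the others.

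In the Goofy-Cre model 9 of 31 lists passed, and only class II ORs held with an estimated correlation (adjusted p = 1.4e-04). With each library left out in turn 7 to 11 lists passed, and 49 of 100 splits, the real one included, gave at least 9. Class II ORs had 61 of 1004 members higher and 879 lower (68 and 888 adjusted over the list alone; median -3.56). Class I ORs had 3 of 121 higher and 107 lower (3 and 110 adjusted over the list alone; median -3.39), with an adjusted p = 0.0878 with an estimated correlation. Mature OSN markers were lower in 13 of 14 (13 adjusted over the list alone; median -0.59), with an adjusted p = 0.124 with an estimated correlation. Of these, Stoml3 fell by 0.86 and Cnga4 by 0.84 (adjusted p = 2.6e-07). Progenitor markers were higher in 8 of 9 (8 adjusted over the list alone; median 0.51), the proneural genes Neurod1 at 0.54 and Ascl1 at 0.51, with an adjusted p = 0.0878 with an estimated correlation. Immature OSN markers were higher in 5 of 12 (6 adjusted over the list alone; median 0.17), Cxcr4 at 0.54, with an adjusted p = 0.249 with an estimated correlation. Cell cycle genes were higher in 12 of 14 (13 adjusted over the list alone; median 0.44), the replication genes Mcm5 at 0.53 and Mcm2 at 0.48, with an adjusted p = 0.123 with an estimated correlation. Bowman gland markers were higher in 1 of 8 (2 adjusted over the list alone; median 0.79), the water channel gene Aqp5 at 0.33 and not past the threshold from TPM values, with an adjusted p = 0.277 with an estimated correlation. Axon guidance genes were lower in 11 of 20 (12 lower and 1 higher adjusted over the list alone; median -0.29), Plxna3 at -0.92 and Efna3 at -0.46, with an adjusted p = 0.319 with an estimated correlation. TAARs were lower in 8 of 12 and higher in 3 (median -1.82), with an adjusted p = 0.472 with an estimated correlation.

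The other Goofy-Cre lists did not pass. Horizontal basal, macrophage, neutrophil, lymphocyte, erythroid and MS4A receptor genes held no called member; S100a9, which rose in the Foxg1-Cre model, had a log2 fold change of -0.46 and did not pass. Sustentacular markers had 4 of 12 higher and 1 lower, the sulfotransferase gene Sult1d1 (-0.73). Microvillous markers had 2 of 9 higher, ensheathing glia markers 2 of 10, fibroblast markers 2 of 10, endothelial markers 1 of 8 and TIF1 genes 1 of 7 (Trim28, 0.25, not past the threshold from TPM values). Respiratory markers had 1 of 7 higher and 1 lower (Ccdc39, -0.52), OR choice regulators 3 of 24 higher and 3 lower (Adcy3 at -0.75), Polycomb genes 1 of 14 higher (Ezh2, 0.25, likewise) and 1 lower (Aebp2, -0.20), dorsal zone genes 1 of 5 each way and vomeronasal receptors 1 of 8 each way. Unfolded protein response genes had 2 of 16 lower, activity genes 1 of 13, ventral zone genes 2 of 4, protocadherins 4 of 56 (0 adjusted over the list alone) and germline genes 1 of 5 (Brdt, -0.72). Median, mean and test differed in sign for OR choice regulators (0.04 and -0.03, direction up), unfolded protein response genes (-0.01 and -0.03, direction up), vomeronasal receptors (-0.23 and 0.15, direction up), MS4A receptors (-0.07 and -0.17, direction up) and germline genes (0.16 and -0.03, direction down).

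**Figure D1:**
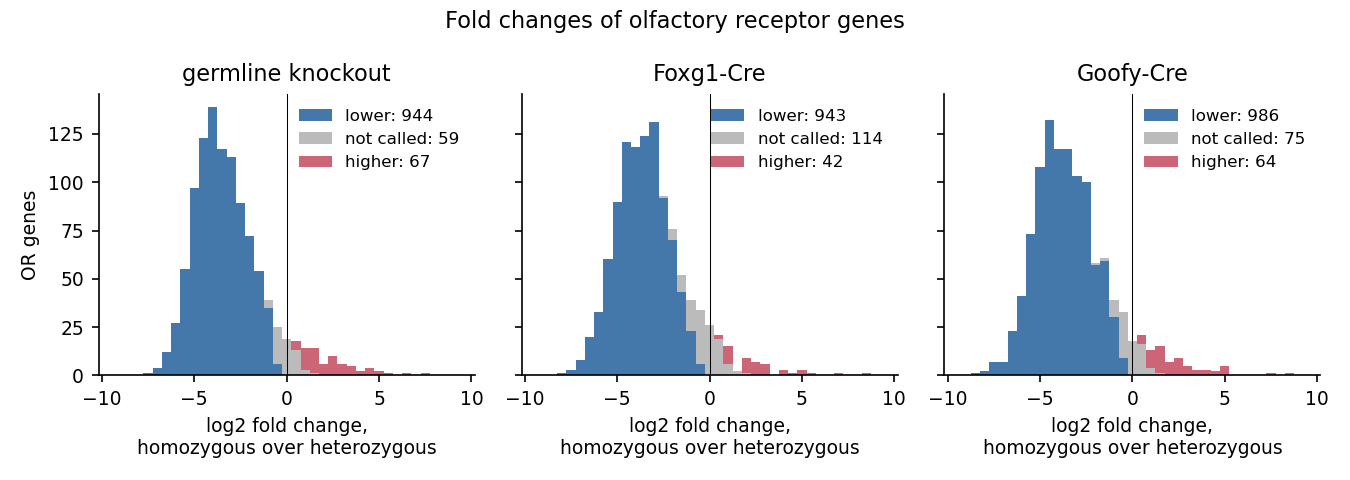
Histograms of the log2 fold change (homozygous over heterozygous, x axis) of all tested OR genes (number of genes, y axis) in the 3 models, split by whether a gene was called lower, called higher or not called. In the germline, Foxg1-Cre and Goofy-Cre models 944, 943 and 986 ORs were lower and 67, 42 and 64 higher.

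ORs as a class took a smaller share of each homozygous library. Their share of normalized counts was 0.777% ± 0.0675 in heterozygous and 0.451% ± 0.0217 in homozygous germline libraries (SD, n = 5 each; exact two-sided permutation p = 0.00794, the smallest possible; 0.0119 after adjustment over 6 tests). In the Foxg1-Cre model it was 0.720% ± 0.111 and 0.379% ± 0.0237 (SD, n = 4 each; exact two-sided permutation p = 0.0286, the smallest possible; 0.0286 after adjustment). In the Goofy-Cre model it was 0.719% ± 0.0326 and 0.375% ± 0.0160 (SD, n = 5 each; exact two-sided permutation p = 0.00794; 0.0119 after adjustment). OR transcripts were also spread over fewer receptors. The effective number of ORs was 687 ± 29.9 against 99.9 ± 8.19 in the germline knockout (SD, n = 5 each; exact two-sided permutation p = 0.00794), 704 ± 33.1 against 101 ± 9.76 in the Foxg1-Cre model (SD, n = 4 each; exact two-sided permutation p = 0.0286) and 631 ± 70.1 against 88.4 ± 6.88 in the Goofy-Cre model (SD, n = 5 each; exact two-sided permutation p = 0.00794), with the same adjusted values as the shares. No homozygous library overlapped a heterozygous one in either measure. Class I ORs made up 9.68% of OR counts in heterozygous and 4.302% in homozygous germline libraries, 11.4% and 5.12% in the Foxg1-Cre model, and 9.24% and 3.81% in the Goofy-Cre model.

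**Figure D2:**
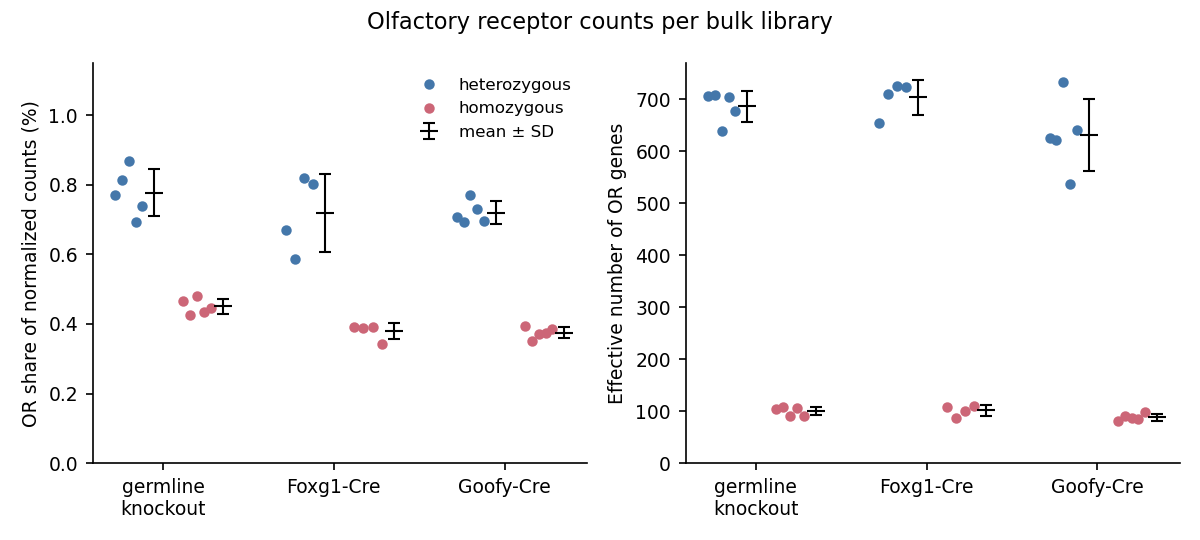
Share of normalized counts on OR genes (percent, y axis) and effective number of ORs (y axis) for each bulk library of the 3 models, heterozygous and homozygous, with points for libraries and bars for the mean ± SD. The homozygous means are 0.451%, 0.379% and 0.375% for the share and 99.9, 101 and 88.4 for the effective number.

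The same receptors could be followed across the 3 models, of which 1062 OR genes were tested in each table. Of these, 905 were lower in all 3 models, where independent lists of 937, 917 and 941 genes would share 716.9. A further 42 were higher in all 3, where independent lists of 67, 42 and 59 genes would share 0.147. The higher ORs lay on 9 chromosomes, and 3 of them were class I genes (Olfr571, Olfr587-ps1 and Olfr650-ps1). On chromosome 1, Olfr433, Olfr430, Olfr427, Olfr231, Olfr258-ps1 and Olfr421-ps1 lay between 174040705 and 174152530. On chromosome 6, Olfr447, Olfr446 and Olfr444 lay between 42908878 and 42956764, and Olfr446 had log2 fold changes of 4.65, 4.16 and 4.43 in the germline, Foxg1-Cre and Goofy-Cre models. These overlaps are counts beside the expected numbers, and differences between the models were not tested.

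The single-cell libraries ask whether the ORs of homozygous germline mice appear in separate cells or together. They held 177.8 M UMIs over 26615 barcodes (heterozygous) and 343.2 M over 32714 barcodes (homozygous), with at least 500 UMIs per barcode. After filtering and doublet removal (11.9% and 19.5% of kept cells), 13137 and 19629 cells were analysed. Mature OSN-like cells, which express Omp and Stoml3, made up 58.7% (95% interval 57.8 to 59.5) of heterozygous and 45.85% (45.15 to 46.55) of homozygous cells. An unnamed cluster nearest to mature OSNs held a further 1.99% and 9.42%, so that the size of this difference depends on the naming of that cluster. Immature OSN-like cells made up 2.37% (2.11 to 2.64) and 10.59% (10.2 to 11.0), and progenitor-like cells 0.845% (0.696 to 1.02) and 2.11% (1.92 to 2.33). Neutrophil-like cells were at 0.251% and 1.51%, while an unnamed cluster nearest to neutrophils, led by S100a8 and S100a9, held 3.72% and 0.642%, so that the direction for neutrophils depends on the naming of that cluster. B cell-like cells were at 0.0685% and 0.805%, macrophage-like cells at 6.39% and 3.63%, and horizontal basal-like cells at 0.434% and 0.7998%. Sustentacular-like cells were at 5.51% and 5.16%. This near-equality depends on 5 clusters left unnamed for their gland genes, which held 8.11% and 2.74% of cells and of which 4 were nearest to sustentacular cells. Microvillous-like cells were at 3.14% and 2.38%, T or NK-like at 1.28% and 0.678%, ensheathing glia-like at 0.617% and 0.576%, fibroblast or osteogenic-like at 0.411% and 0.474%, and erythroid-like at 0.343% and 0.397%. Unnamed clusters held 19.7% and 25.0% of cells, and those nearest to an OSN class 4.62% and 17.7%. With 1 library per genotype these differences have no test, and yields of cell types can differ between preparations.

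Most homozygous mature OSN-like cells held several ORs at once. Exactly 1 OR with at least 3 UMIs was found in 79.5% of 7707 heterozygous and 9.63% of 9000 homozygous cells, at median depths of 9525 and 10240 UMIs. The share with 2 or more ORs was 14.5% (95% interval 13.8 to 15.4) in heterozygous and 82.2% (81.4 to 83.0) in homozygous cells. Sustentacular-like cells, which should lack ORs, had shares of 14.9% (12.4 to 17.7) and 15.0% (12.9 to 17.4) at median depths of 12116 and 12851 UMIs. At these unequal depths the heterozygous mature share was no higher than this background. The spread differed: 4 or more ORs were held by 0.558% of heterozygous mature and 7.18% of heterozygous sustentacular-like cells. In heterozygous mature cells with 2 or more ORs, the second lay within 1 Mb of the first in 20.3%, against 5.44% when shuffled. In homozygous ones these shares were 6.5% and 3.29%. Not all second ORs of the heterozygous cells are therefore accounted for by background. Reads shared between neighbouring paralogs may give such pairs, which was not tested. With doublets kept, the sustentacular shares were 25.98% and 46.1%. After thinning to 3000 UMIs per cell, the mature shares were 11.5% and 64.4%, and the sustentacular shares 8.46% and 2.36%. Shallower cells were left out, 1223 of 7707 heterozygous and 985 of 9000 homozygous mature cells. Among sustentacular-like cells, 180 of 724 and 207 of 1013 were left out. At this equal depth the heterozygous mature share lay above the heterozygous sustentacular one, with overlapping intervals (10.7 to 12.3 and 6.26 to 11.1). Immature OSN-like cells had 8.36% and 16.7% with all counts. Thinned, they had 1.83% (0.597 to 4.22) and 4.56% (3.68 to 5.59), the latter above the 2.36% (1.43 to 3.66) of thinned homozygous sustentacular-like cells. With doublets kept and no thinning, the homozygous immature share was 24.7%, below the 46.1% of sustentacular-like cells. Median depths differed there (11142 and 26122 UMIs), so that it stays open whether immature cells exceeded the background. Homozygous mature cells held a median of 5 ORs and at most 24, heterozygous ones a median of 1 and at most 12. The most abundant OR of a cell held a median of 97.8% of its OR UMIs in heterozygous and 35.3% in homozygous cells, while the median number of OR UMIs per cell was 71 and 60. The mature class differed in its clusters: cluster 5 held 3.49% of heterozygous and 21.5% of homozygous mature cells. The share with 2 or more ORs was 16.5% and 90.9% in cluster 0, 15.8% and 85.9% in cluster 1, 5.16% and 35.1% in the shallow cluster 2, 11.5% and 97.2% in cluster 5, and 23.8% and 77.9% in cluster 6. In cluster 2, 41.4% of homozygous cells held no OR.

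**Figure D3:**
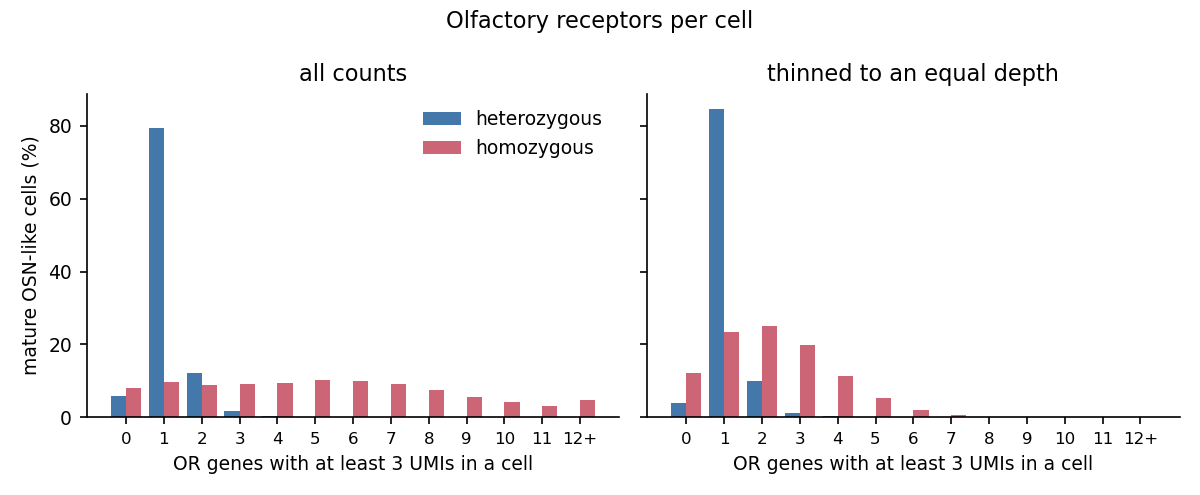
Percent of mature OSN-like cells (y axis) by the number of OR genes with at least 3 UMIs in the cell (x axis), for the heterozygous and homozygous single-cell library, with all counts and after thinning to 3000 UMIs per cell. With all counts 79.5% of heterozygous and 9.63% of homozygous cells held exactly 1 OR.

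The receptors in homozygous cells came from a small set. Over 7247 cells with an OR in each library, 920 different ORs were the most abundant in at least 1 heterozygous cell, against 238.6 on average over draws of homozygous cells, and the effective numbers were 614 and 24.2. The most frequent was Olfr591 in heterozygous cells, with 0.897%, and Olfr446 in homozygous cells, with 21.2%, followed by Olfr1507 with 10.38%. Olfr446 was held by 0.441% of heterozygous and 60.6% of homozygous mature OSN-like cells, against 10.8% of homozygous sustentacular-like cells; after thinning, the homozygous shares were 40.6% and 1.86%. Olfr427 was detected in 0 of 7707 heterozygous cells, which does not bound the share that transcribes it because droplets miss molecules, and in 53.4% of homozygous ones (8.59% in sustentacular-like cells; 18.3% and 0.372% after thinning). Olfr874 was held by 45.3% of homozygous cells, Olfr525 by 37.7%, Olfr332 by 36.6%, Olfr447 by 23.1%, Olfr1406 by 19.4% and Olfr231 by 17.4%. Each was held by 0.363% or less of heterozygous ones. After thinning, the homozygous shares were 29.8%, 21.6%, 14.8%, 6.84%, 3.64% and 7.12%, in the same order. Homozygous sustentacular-like cells held these ORs at 3.26% (Olfr231) to 8.39% (Olfr332), and at 1.365% or less after thinning. Olfr446, Olfr874, Olfr332, Olfr1406 and Olfr231 lie outside the naming rule and were chosen after their values were seen. Of 24 ORs at 50 CPM or more and over 2-fold higher in homozygous mature OSN-like cells and tested in all bulk tables, 17 were among the ORs higher in all 3 bulk models (0.826 expected), and 19 of 20 lower ones were among those lower in all 3 (17.4 expected).

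**Figure D4:**
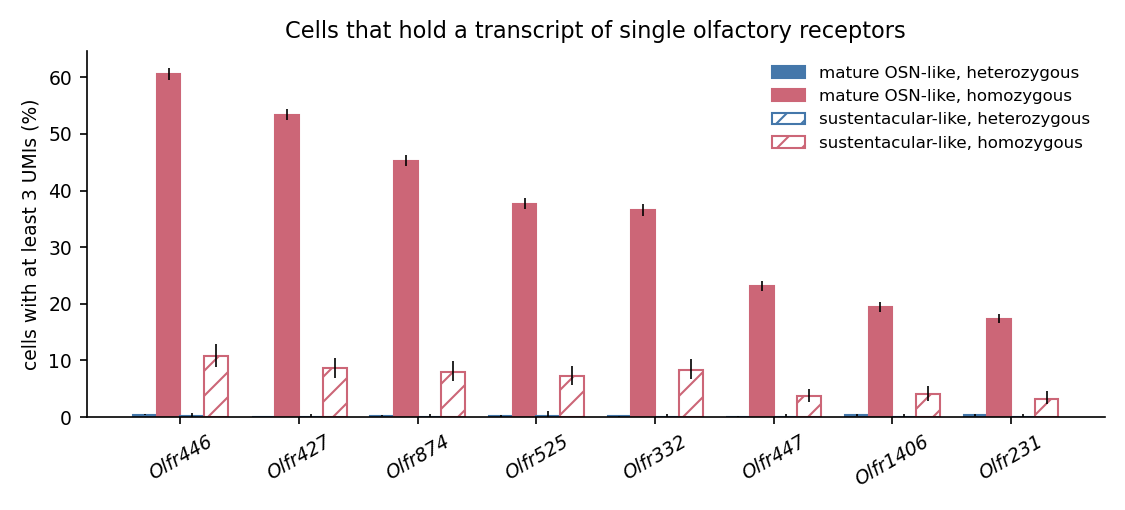
Percent of cells (y axis) with at least 3 UMIs of each of 8 ORs (x axis) in mature OSN-like and sustentacular-like cells of the heterozygous and homozygous libraries, with exact 95% intervals as bars. Olfr446 and Olfr427 are held by 60.6% and 53.4% of homozygous mature OSN-like cells and by 10.8% and 8.59% of homozygous sustentacular-like cells.

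In mature OSN-like cells Trim66 (ENSMUSG00000031026) stood at 187 CPM in the heterozygous and 193 in the homozygous library. The ORs with the highest ratio of homozygous to heterozygous CPM were Olfr427 (0 to 406 CPM), Olfr525 (6.16 to 523), Olfr368 (2.41 to 233), Olfr447 (2.32 to 191) and Olfr464 (4.14 to 293.7). The ORs with the lowest ratio had few molecules left: Olfr672 went from 102 CPM to 0.0223 (interval 0.00270 to 0.0806; 2 UMIs), Olfr1046 from 88.1 to 0.0112 (0.000282 to 0.0622; 1 UMI), Olfr1357 from 86.1 to 0.0223 (2 UMIs), Olfr24 from 80.04 to 0.0223 (2 UMIs) and Olfr586 from 107 to 0.3905 (35 UMIs). H2-M1 went from 0.0133 CPM (0.000336 to 0.0739; 1 UMI) to 113.5, against 5.83 in homozygous sustentacular-like cells, and Vmn2r27 from 3.14 to 358, against 21.9. AW551984 went from 0.0265 CPM (2 UMIs) to 59.3, Taar2 from 2.51 to 159, the cilia-associated gene Fam183b from 5.02 to 99.4, the growth regulator gene Tbrg1 from 70.1 to 305, the channel-associated gene Tcaf1 from 31.1 to 102 and the interferon-inducible gene Ifi27 from 51.1 to 150.1. The complement regulator gene Cd55, which marks cluster 6, went from 148 to 31.1 CPM, Gas1 from 67.0 to 25.3, Arrdc3 from 65.4 to 26.5 and the dorsal zone enzyme gene Nqo1, which marks cluster 0, from 1002 to 461. Hjurp went from 173 to 38.2, Aldh1a3 from 67.1 to 16.7, Tomm22 from 173 to 63.4 and Ptpn2 from 51.0 to 20.9. All 8 of these genes were also lower in homozygous sustentacular-like cells, with separate intervals: Cd55 went from 61.3 to 41.4 CPM there, Gas1 from 68.3 to 51.5, Arrdc3 from 110.1 to 93.3, Nqo1 from 181 to 108, Hjurp from 46.9 to 18.3, Aldh1a3 from 19.3 to 5.50, Tomm22 from 152 to 61.1 and Ptpn2 from 33.3 to 14.3. The neuronal markers Omp (1603 to 793.5 CPM) and Stoml3 (2108 to 876) were also lower in these sustentacular-like cells. In immature OSN-like cells Nqo1 went the other way, from 157 to 344 CPM. The mature marker gene Omp stood at 5269.9 and 5095 CPM. OR transcripts as a whole made up 0.968% of mature OSN-like UMIs in the heterozygous and 0.695% in the homozygous library.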

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

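A sample was set apart here when its gap to the nearest other sample of its group took up more of the group's range than Dixon's 95% critical value allows. Of 434 groups of libraries tested, 29 held such a sample, which is 6.68%, where chance marks about 1 in 20 groups. All tests of explanations in this part, with those on other splits of the samples, were written after the results were seen. In the germline knockout, homozygous replicate 3 stood apart in the mature OSN level, at 13.9 against 13.7 in the others. Homozygous replicate 1 had 4.98 normalized counts of Olfr250, against 0 to 1.13 in the others. Heterozygous replicate 1 had 324.4 of Olfr810 against 360 to 373. Heterozygous replicate 2 had 177.2 of Olfr1321 against 259 to 273. Homozygous replicate 4 had 8.67 of Taar7f against 12.4 to 13.7. Heterozygous replicate 3 had 248.0 of Vmn2r27 against 40.2 to 81.7. Homozygous replicate 5 had 2713 of Hes6 against 3935 to 4355, and 2567 of Ccdc39 against 2079 to 2147. Homozygous replicate 2 had 71.9 of Olfr1509 against 36.9 to 44.9. Homozygous replicate 3 had 74.7 of Olfr17 against 32.5 to 44.2.

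In the Foxg1-Cre model, homozygous replicate 4 stood apart in the OR share, at 0.344% against 0.389% to 0.392%. It also had 8518 normalized counts of Olfr427, against 9676 to 9860 in the others. Homozygous replicate 3 had 1.01 of Olfr224 against 0. Heterozygous replicate 2 had 137.4 of Olfr427 against 11.2 to 15.4, and 89.8 of Olfr421-ps1 against 2.88 to 8.54. Heterozygous replicate 4 had 73.3 of Srp54b against 4.33 to 13.3. Heterozygous replicate 1 had 6354 of Marcksl1 against 7456 to 7593, and 1.90 (1.897) of Ddx3y against 1945 to 2033.

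In the Goofy-Cre model, homozygous replicate 3 had 3.39 normalized counts of Olfr250 against 0, and 8137 of Olfr51 against 4800 to 5219. Heterozygous replicate 3 stood apart in 7 genes: Olfr464 (593.3 against 455 to 493), Krt25 (394.4 against 33.1 to 59.3), Taar7b (311.2 against 199 to 215), Efna3 (22834 against 18281 to 18729), Olfr160 (608.4 against 399 to 414), Olfr17 (1993 against 1127 to 1276) and Olfr78 (547.9 against 230 to 280). Without this library 3913 genes were called, 1504 higher and 2409 lower, and 68 ORs were higher and 977 lower. Ddx3y stood apart at 4.16 in heterozygous replicate 1, against 2771 to 3223, and at 0 in homozygous replicate 1, against 2464 to 3316. S100a9 had log2 fold changes of 1.27 in the Foxg1-Cre and -0.46 in the Goofy-Cre model, where it did not pass; it was the only gene of 119 compared whose homozygous libraries all lay on opposite sides of the heterozygous mean in 2 models, and the difference was not tested.

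The first pattern weighed is the fall of OR genes in homozygous bulk libraries. Fewer mature neurons, if lost evenly over the ORs they hold, could lower ORs only as far as the other transcripts of these neurons. The median log2 fold change of ORs was -3.45 in the germline knockout, -3.39 (-3.3853) in the Foxg1-Cre and -3.54 in the Goofy-Cre model. The lowest mature OSN marker was Cngb1 at -0.72, Cngb1 at -0.79 and Ano2 at -0.89. A loss of neurons spread evenly over the ORs they hold is therefore excluded as the whole cause of the gene-level fall. Mature neurons share these markers, which cannot tell whether neurons holding particular ORs were lost or replaced. The authors' size factors are excluded too, since the median nearest to 0 over both other scalings and all models was -3.03. For the OR share, whose log2 ratio was -0.78 with an SE of 0.064 in the germline knockout, -0.92 with 0.124 in the Foxg1-Cre and -0.94 with 0.040 (0.03998) in the Goofy-Cre model, fewer mature neurons and less OR transcript per neuron cannot be told apart: the ratios lie below all 14 mature markers in each model (marker medians -0.39, -0.52 and -0.59), but less than 2 SE below the lowest. In single cells the OR share within mature OSN-like cells was 0.968% in heterozygous and 0.695% in homozygous cells, which argues against fewer neurons as the whole cause but rests on 1 library per genotype.

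The second pattern weighed is several ORs in single homozygous mature OSN-like cells. Doublets are excluded as the whole cause: 64.3% of these cells held 4 or more ORs, at a nominal doublet rate of 19.5%. After thinning, 2.36% of homozygous sustentacular-like cells held 2 or more ORs, against 64.4% of mature OSN-like cells, which argues against free RNA as the whole cause. Doublet removal had, however, also taken out sustentacular-like cells with ORs. With doublets kept and no thinning, the shares were 46.1% and 81.5%. No thinned shares were computed with doublets kept, so that free RNA is not fully excluded. Reads shared between neighbouring paralogs cannot give ORs of different chromosomes. Of the homozygous cells with 2 or more ORs, 98.2% (97.8 to 98.5) held ORs of at least 2 chromosomes, so that such reads are excluded as the whole cause there. The share was 71.1% (68.3 to 73.8) in heterozygous cells with 2 or more ORs, whose ORs per cell were fewer. Reads shared between paralogs on different chromosomes were not examined. The Trim66 genotype is the difference the design names, and as a hypothesis its loss may allow several ORs per neuron, but with 1 library per genotype no test was made.

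The third pattern weighed is the rise of H2-M1 and Vmn2r27. Vomeronasal tissue carried along is excluded, since the summed counts of 579 other vomeronasal receptor genes had log2 ratios of -0.33, -0.48 and -0.34 in the 3 models. The vomeronasal channel gene Trpc2 was at 0.228 and 0 mean normalized counts in the germline knockout and at 0 in the other models. Whether its reads can be counted in these data was not tested, so that Trpc2 adds no support. A larger share of immature neurons is excluded as the whole cause, since the immature OSN marker with the highest log2 fold change was Cxcr4 at 0.54, against 5.22 or more for Vmn2r27 and 8.28 or more for H2-M1. As a hypothesis, the rise may belong to the loss of Trim66 itself, which was not tested apart from the genotype.

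Other splits of the same libraries were fitted to see whether a chance split gives results as large. In the germline knockout 1 of 100 splits, the real one, gave 2408 called genes, 67 higher ORs or 944 lower ORs. The highest count of the others was 0 for each. In the Foxg1-Cre model 1 of 35 splits, the real one, gave 1902 called genes (highest other 5), 42 higher ORs (0) or 943 lower ORs (0). Heterozygous replicates 3 and 4 of that model may be technical replicates of 1 sample, so that its libraries may not be independent. In the Goofy-Cre model 1 of 100 splits, the real one, gave 3947 called genes, 64 higher ORs or 986 lower ORs. The highest counts of the others were 3, 0 and 0. The other splits mix the genotypes, so that a real difference widens the spread within their groups and leaves few calls. These are the smallest shares possible, and they make a chance split unlikely only if the libraries are independent samples. Over splits of all models together, 1 of 100, the real one, gave 905 ORs lower or 42 higher in all 3 models (highest other 0); since no other split of any model called an OR, this follows from the counts per model and adds no test of the shared set. For the number of lists past the threshold chance was not excluded: 13 of 100 germline splits gave as many as the real 13 (highest other 16), 18 of 35 Foxg1-Cre splits as many as 9 (highest other 16) and 49 of 100 Goofy-Cre splits as many as 9 (highest other 17).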

How the results depend on the processing

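The sex term, the averaged Foxg1-Cre replicates, the edgeR and DESeq2 counts for ORs and the count without the shallow cluster were tests chosen after the data were seen. In every bulk model and under each alternative run, far more ORs were lower than higher. Genes called came to 2441, 1860 and 3922 with edgeR in the germline, Foxg1-Cre and Goofy-Cre models, to 3003, 2608 and 4531 with DESeq2, to 2430, 1910 and 3960.0 with a pseudocount of 5, to 2371, 1875 and 3828 without a filter, to 2254, 1795 and 3994 with the same total, and to 2270.0, 1991 and 3940.0 with a sex term. From TPM values they came to 1396 in the germline knockout, against 2408; the cause was not tested. With the Foxg1-Cre heterozygous replicates 3 and 4 averaged, since they may be technical replicates, 1424 genes were called, 1422 of them the same, and the OR share differed by -0.31 (exact two-sided permutation p = 0.0286, the smallest possible). With the mature OSN level as a covariate, 988, 475 and 473 genes were called, with 47 ORs higher and 801 lower, 30 and 353, and 16 and 375. The median OR log2 fold change was -3.29, -2.83 and -3.90 with it, against -3.45, -3.39 and -3.54. The median SE went from 0.25 to 0.54, from 0.31 to 0.73 and from 0.29 to 1.18. In each model the lowest heterozygous level (14.01, 14.58 and 15.41) lay above the highest homozygous one (13.90, 14.37 and 15.01). The level is therefore hard to separate from the genotype, so that these fits cannot show whether the change itself is smaller. With an estimated correlation 2, 1 and 1 lists passed. With replicate number as a block, 2140.0, 1396 and 3672 genes were called, 202 of the Foxg1-Cre ones higher against 399, the OR share differed by -0.326, -0.341 and -0.344, and the effective number by -586.6, -602.2 and -542.8 (exact two-sided sign-flip p = 0.0625, 0.125 and 0.0625, the smallest possible); the numbers do not pair the samples, since same-numbered libraries correlated between -0.37 and 0.37, 3 of 14 pairs over 0.1, and not every library correlated best with its own number. Leaving out each library in turn gave 1886 to 3016, 1404 to 2380.0 and 3215 to 3913 called genes, 63 to 69, 38 to 43 and 58 to 68 higher ORs, 933 to 951, 916 to 947 and 971 to 984 lower ORs, 8 to 12, 10 to 14 and 7 to 11 lists, share differences of -0.347 to -0.303, -0.385 to -0.307 and -0.350 (-0.3503) to -0.331, and effective number differences of -598.7 to -581.2, -618.5 to -595.2 and -566.5 to -517.2. The lists came to 8 without germline homozygous replicate 5 and to 14 without Foxg1-Cre homozygous replicate 4. Trim66, never called, had a log2 fold change of -0.01 (-0.0074) without germline heterozygous replicate 4, -0.03 (-0.0325) without heterozygous replicate 5 and -0.01 (-0.0052) without homozygous replicate 2, in a range of -0.03 to 0.13 over the libraries left out. Over the named genes and alternatives, 1012 values stayed on their side of the threshold in the germline knockout, 807 in the Foxg1-Cre and 1164 in the Goofy-Cre model, while calls were lost in 54, 74 and 35 cases. Calls were gained by Olfr1508 in the germline knockout in 3 cases, the block and leaving out heterozygous replicate 2 or 4, and by Olfr545 in the Foxg1-Cre model in 1, leaving out heterozygous replicate 2. The losses fell on Moxd1, Bglap, Trim28, Cbr2, Ezh2, Rtp2, Krt14, Brdt, Lrrc3b, Foxj1, Foxi1, Cxcr4 and Ccdc39 in the germline knockout, on Pecam1, Brdt, S100a5, Marcksl1, Krt5, C1qc, Sult1d1, Ncam2, Hba-a1, Rtp1, Sox11, Ccdc39, Ezh2 and Col2a1 in the Foxg1-Cre model, where 10 named genes lost their call without heterozygous replicate 3 and 11 without replicate 4, and on Olfr1508, Ascl3, Ddit3, Egfl7, Olfr151, Trim28, Pcdhb1, Ezh2 and Aqp5 in the Goofy-Cre model. In single cells, the share of mature OSN-like cells with 2 or more ORs was 88.6% in homozygous and 20.4% in heterozygous cells at 2 UMIs, 72.7% and 11.5% at 5 UMIs, 87.6% and 15.9% with the gene filter at 2 times 500 genes, 64.4% and 11.5% thinned, 89.7% and 17.1% without shallow clusters, and 15.5% in heterozygous cells with doublets kept, when the sustentacular-like shares were 46.1% and 25.98%. Different top ORs numbered 249.15 and 924 at 2 UMIs, 228.25 and 908 at 5, 251.35 and 928 with doublets kept, 220.2 and 904 with the stricter gene filter, 198.7 and 879 thinned, and 189.4 and 880.0 without shallow clusters. Their effective numbers were, in the same order, 25.3 and 618.0, 22.9 and 607.4, 25.7 and 624.05, 23.5 and 601.3, 22.6 and 591.6, and 22.4 and 588.1. Mature OSN-like cells made up 40.1% and 47.2% with the resolution doubled, 42.3% and 56.7% with doublets kept, and 60.1% of heterozygous cells with the stricter gene filter. Immature OSN-like cells made up 9.705% and 2.06% with the resolution halved, 11.9% of homozygous cells with it doubled and 2.92% of heterozygous cells with doublets kept, and progenitor-like cells 2.49% of homozygous cells with doublets kept and 0.693% of heterozygous cells with the stricter gene filter. The causes of these shifts were not tested. Depth limits ORs with few reads, whose fold changes are understated, and the number of ORs seen in a cell.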

Other observations

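The values in the first 2 paragraphs and the test of neighbouring genes were chosen after the data were seen, while the test of holding cells was written before its result. Some receptors had more CPM in immature than in mature OSN-like cells of the homozygous single-cell library, and others had none in either. Olfr672 stood at 11.8 CPM (exact interval 10.5 to 13.2) in immature and 0.0223 in mature homozygous cells. Olfr1046 stood at 5.20 (4.34 to 6.19) and 0.0112, and Olfr586 at 6.02 (5.09 to 7.08) and 0.3905. Olfr15 was at 10.44 and 0.614, Olfr160 at 4.63 and 1.68, and Olfr17 at 2.62 and 0.0223. Olfr1357 was low in both, with 0.0819 CPM from 2 UMIs in immature cells. Olfr16 and Olfr73 had 0 UMIs in both classes, and Olfr2 had 0 in immature and 4 in mature cells.

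The following 5 genes are not ORs and lie near ORs higher in all 3 models; they were picked for their values, and the other neighbouring genes were not counted or tested. AW551984, on chromosome 9 between Olfr957 and Olfr961, had log2 fold changes of 4.12, 3.56 and 3.82 in the germline, Foxg1-Cre and Goofy-Cre models. Trim68 (ENSMUSG00000073968.4, chromosome 7, 102677582 to 102687327), near Olfr571, had 1.84, 1.68 and 1.54 (adjusted p = 3.1e-11, 2.6e-07 and 1.1e-08). Tcaf1 (ENSMUSG00000036667.14, chromosome 6, 42668002 to 42710088), near Olfr447, had 0.99, 0.94 and 0.91 (adjusted p = 6.2e-09, 9.0e-05 and 6.9e-09). Tbrg1 (ENSMUSG00000011114.18, chromosome 9, 37648763 to 37657312), near Olfr874, had 0.97, 0.80 and 0.74 (adjusted p = 5.2e-08, 9.7e-05 and 5.4e-07). Fam183b, near Olfr323, had 0.63, 0.68 and 1.02 and did not pass in the Foxg1-Cre model (adjusted p = 0.0144, 0.193 and 0.0119). Some nearer ORs fell. Olfr78 (chromosome 7, 102738511 to 102759471) lies between Trim68 and Olfr571. It had a log2 fold change of -1.08 in the Foxg1-Cre model and did not pass in the germline knockout. Olfr160 (chromosome 9, 37708964 to 37716250) lies between Tbrg1 and Olfr874 and had -2.15 in the Foxg1-Cre model.

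A first hypothesis was that the ORs higher in all 3 models lie next to each other. Of these 42 genes, 20 had another within 100 kb, against 9.10 on average in 10000 random draws of as many from 1062 tested ORs (one-sided permutation p = 0.0027). The grouping may therefore go with position in the genome, and the random draws did not hold local gene density fixed.

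A second hypothesis was that these receptors rise because more cells hold them, with no more transcript in each. For 7 of the 42 genes, those with at least 20 holding cells in both libraries, the median ratio of UMIs per holding cell was 0.207 (quartiles 0.0995 to 0.269). The median ratio of the share of mature OSN-like cells that held the receptor was 26.9. These values leave the hypothesis open. The other genes, such as Olfr427 with 0 heterozygous holding cells, could not enter, and cells that hold a receptor only as background would lower the UMIs per holding cell; 10.8% of homozygous sustentacular-like cells held Olfr446.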
